A study of Mus musculus with 10 samples.

How the data were processed

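Single-cell RNA sequencing was done on cerebellar tumours of SmoA1 mice, which express an activated form of Smoothened, the signal transducer of the hedgehog pathway. Mice received 1 Gy of radiation or a sham procedure, and tumours were collected 5 h or 24 h after irradiation. The labels place the sham tumours at 5 h, so the 24 h group had no sham group of its own time. Per the labels, tissue was dissociated with papain and libraries were made with 10x Chromium 3' chemistry, in which each molecule carries a unique molecular identifier (UMI). The 10 libraries comprised 3 sham libraries (A1, A5 and B2), 4 libraries at 5 h (A4, B2, C1 and C2) and 3 at 24 h (A3, B1 and D3). The codes are those of the labels, and a code shared between groups was not taken as a pairing. The labels do not say that the libraries came from separate animals, so p values measure the spread between these libraries, which may be partly technical.

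The deposited matrices hold raw UMI counts per gene and cell barcode, with no normalization. Per the submitters' processing notes, the genome was mm10 and the software Cell Ranger 5.0.1. Per the file headers, Cell Ranger 3.1.0 wrote 8 matrices and version 3.0.2 wrote those of 5 h A4 and sham A5. The authors' feature tables had 2 sizes, 28010 features in these 2 libraries and 31053 in the other 8. The smaller tables included 12 reporter entries, which were at 0. The annotation used for counting is not given in the sources used here. The 27514 genes present in every table were used, and they held between 99.65% and 99.90% of the UMIs of a library. No column was left without a sample. Gene positions were taken from the GENCODE vM21 annotation of mm10.

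The libraries held 91306 barcodes in all. Cells with at least 500 genes and at most 15% mitochondrial counts were kept, which left 80621. The mitochondrial limit had no effect in sham A5 and 5 h A4, where mitochondrial genes were at 0. Doublets were scored per library against simulated pairs of cells and removed at an expected rate of 0.8% per 1000 cells, which marked between 1.29% and 11.8% of a library. Cells were clustered on 2000 variable genes, 40 principal components, 20 nearest neighbours and Leiden resolution 1, with seed 1. Clusters were named from marker lists fixed before the data were examined, by the markers among their 10 leading genes and the median fold of each list against other cells. A cluster was called granule-lineage where at least 3 lineage markers were detected and no list other than the mature granule neuron and erythrocyte lists was raised in it by a median log2 fold of 1.5 or more. In the granule-lineage clusters 3, 6 and 16 the mature granule neuron list had the highest median log2 fold (1.39, 1.53 and 1.41), and in 2, 5, 14 and 19 the erythrocyte list had it. Clusters that met no rule stayed unnamed and are in no class. So did shallow clusters with no marker of the class among their leading genes. Such were clusters 9 and 22, at 0.203 and 0.276 of the median depth of their libraries, although 12 and 11 lineage markers were detected in them. Other unnamed clusters were not shallow. Cluster 23 (978 cells, relative depth 2.90) had as many microglia as border macrophage markers among its leading genes. Cluster 27 (520 cells) came almost wholly from 24 h B1 (512). Clusters 35, 36 and 37 (122, 84 and 31 cells) held only cells of sham A5 and 5 h A4. The highest list was the astrocyte list in cluster 35 and the endothelial list in cluster 37, and the second highest in cluster 36 was the oligodendrocyte progenitor list, so these classes are undercounted in those 2 libraries. The word "-like" in a class name means that the class was assigned from these markers. Leading genes of the 19 granule-lineage clusters were also taken against cells outside the lineage, a reference chosen after the data were seen, and no other class had more markers among them than the lineage. In clusters 12, 14 and 17, which held all lineage cells of sham A5 and 5 h A4, neither the lineage nor another class had a marker among the leading genes.

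UMI counts were summed per library and class, because cells are not replicates. The sums were tested with edgeR's quasi-likelihood test, with TMM normalization, low genes removed by filterByExpr, and all groups in one fit. Benjamini-Hochberg adjusted p values under 0.05 were called. Every adjusted p value of a gene comes from this test unless another tool is named. Other classes were tested where at least 30 cells per library were present in at least 2 libraries of both groups. Of 36 gene lists fixed before the data were examined, 19 held cell type markers and 17 held pathways or processes. Lists with at least 5 tested members were tested with camera, limma's competitive set test, at a preset correlation of 0.01 and again with an estimated correlation. The directional fry test was run as an alternative. Counts of list members were made over all tested genes and adjusted over the list alone.

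Shares of cell classes and shares of cells with a UMI were compared with two-sided exact permutation tests over libraries, adjusted over the classes or genes of a comparison. For shares of cells with a UMI, each granule-lineage cell was thinned to 1500 UMIs, and shallower cells were left out, so that between 70.4% (sham A5) and 99.7% of a library's cells entered. Levels are in CPM, the summed UMIs of a gene scaled to a common library total, given as mean ± SD over libraries. Fold changes are on the log2 scale with their standard errors (SE).

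Genes were named by a rule fixed before the data were examined. It took 9 fixed genes, the up to 8 largest called changes each way with a mean log2 CPM of at least 4 and groups that did not overlap, and up to 3 called members of each list. Comparisons of 24 h with 5 h and of other classes took up to 5 each way, at a mean log2 CPM of at least 5. The text drops some of these for length, by order within the rule, and 1 is not reported here. Other genes are named with the words that they were chosen after their values were seen.

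The design fixed in advance fits all 10 libraries, and those counts are given for each comparison. Sham A5 and 5 h A4 differed from the other 8 libraries in how genes with and without introns were counted. Their barcodes differed too: 0 began with AAACCC in both, against 3 to 17 in each other library. In turn, 12 (sham A5) and 1 (5 h A4) began with AAACCT, against 0 in each other library. The pair may thus also differ in how the libraries were made, which was not tested. The genes and lists of the granule lineage are therefore described from the other 8, termed the exon-counting libraries (sham n = 2, 5 h n = 3, 24 h n = 3). Leaving out this pair was an alternative planned from the sizes of the feature tables. Describing genes from it, repeating every alternative on it and a covariate for library type were chosen after seeing the data. So were the addition of unnamed granule-marker clusters and leaving out both 24 h libraries without Ddx3y UMIs. Naming unnamed clusters 23, 26.1, 35 and 37 by their highest list was also chosen then. The alternatives listed in advance were another normalization, DESeq2, limma-voom, no filter on low counts, the compared groups alone, the letter of the library code as a block, other cell filters, doublets kept, other sets of cells, equal depth, and leaving out each library in turn.

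The tests were run on simulated counts drawn from the means of these libraries, with 100 genes changed 1.5-fold and 100 changed 3-fold. With 10 libraries, no changed gene was recovered in any comparison (0 of 100 at either size). With the exon-counting libraries, 7 of 100 genes changed 1.5-fold and 85 of 100 changed 3-fold were recovered for 5 h against sham (14800 genes), with 10 false calls. For 24 h against sham (14816 genes) the numbers were 8 and 88, with 10 false calls. For 24 h against 5 h they were 16 and 90, with 9 false calls. A 1.5-fold change was thus mostly below what this depth and number of libraries detected. Within each group the counts of every pair of libraries differed by more than sampling noise (chi-square per degree of freedom between 15.3 and 967). Separately made libraries do so whatever their origin, so this does not show that they came from separate animals. Each library was counted as 1 replicate.

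Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9. R 4.3.3 was used with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and the data.table package, version 1.17.8.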

Results

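The data comprised single-cell RNA profiles of hedgehog-driven medulloblastoma, a tumour of the cerebellar granule neuron lineage, from SmoA1 mice. Tumours collected 5 h and 24 h after 1 Gy of radiation were compared with sham-treated tumours, to ask how tumour cells and the cells around them respond to a single dose over time. The 3 sham libraries held 119676156 (A1), 12693063 (A5) and 99334738 UMIs (B2). The 4 libraries at 5 h held 5751165 (A4), 101031813 (B2), 70225798 (C1) and 85155442 (C2), and the 3 at 24 h held 81751168 (A3), 95887918 (B1) and 20318019 (D3). Median UMIs per barcode ranged from 1838 in sham A5 to 9096.5 in sham B2. Among the kept cells, 59502 were granule-lineage tumour-like, from 630 in 24 h D3 to 12305 in sham A1.

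Sham A5 and 5 h A4 stood apart from all other libraries. Of 160 single-exon genes expressed elsewhere, 127 (79.4%) were at 0 in sham A5 and 129 (80.6%) in 5 h A4, against 0 in each of the other 8 libraries. Among 6433 genes with introns, 2.18% and 3.11% were at 0. Actb, an abundant cytoskeletal gene, was at 112 and 449 CPM in these libraries, against 4446 to 6895 CPM in the others. Atoh1, a single-exon gene and the master transcription factor of granule neuron progenitors, had 0 UMIs in both. The 24 h group held no library of this kind. The exon-counting libraries are the other 8. The values of granule-lineage genes below are theirs, except for shares of cells with a UMI and where all libraries are named.

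**Figure D1:**
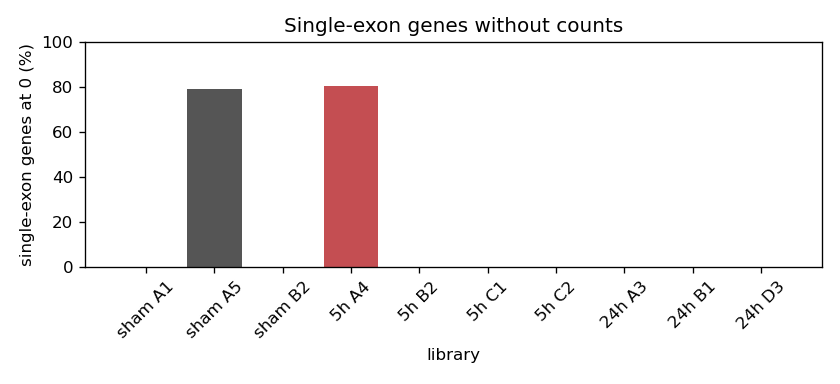
Percent of 160 single-exon genes without a count (vertical axis) in each of the 10 libraries (bars, coloured by group). Sham A5 reached 79.4% and 5 h A4 80.6%, and the other 8 libraries were at 0.

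The measured shares of cell classes differed between times, though no difference passed the adjusted test. Granule-lineage tumour-like cells made up 90.5% ± 4.24 of kept cells in sham (SD, n = 3), 81.1% ± 5.24 at 5 h (n = 4) and 55.0% ± 14.7 at 24 h (n = 3). Microglia-like cells, the brain's resident macrophages, made up 1.77% ± 0.76, 3.64% ± 1.03 and 8.62% ± 1.40. Border macrophage or monocyte-like cells made up 0.134% ± 0.0555, 1.29% ± 1.20 and 4.26% ± 2.12, astrocyte-like cells 0.609% ± 0.669, 1.79% ± 1.62 and 6.59% ± 3.76, and neutrophil-like cells 0.0577% ± 0.0500006, 1.35% ± 1.47 and 2.04% ± 1.02. Single libraries moved these means: at 5 h the border macrophage share was 0.720% without A4, and without C1 the neutrophil share was 0.611% and the astrocyte share 1.10%, while the astrocyte share in sham was 0.238% without B2. Sham A5 and 5 h A4 counted 3 and 0 astrocyte-like cells because 66 and 56 of their cells lay in cluster 35, which stayed unnamed although the astrocyte list was highest there. With clusters 23, 26.1, 35 and 37 given the class of their highest list, a repeat chosen after seeing the data, astrocyte-like cells made up 1.001% ± 0.504, 2.55% ± 1.14 and 6.59% ± 3.76, and microglia-like cells 2.24% ± 1.07, 4.88% ± 1.49 and 10.8% ± 0.461. Cluster 23, the microglia-like part of this, had as many border macrophage as microglia markers among its leading genes; counted as border macrophages, it raised their shares to 0.602% ± 0.461, 2.53% ± 0.871 and 6.39% ± 0.430. The share of granule-lineage cells was lower in each 24 h library than in each library at 5 h (exact permutation p = 0.0286, the smallest this design allows; adjusted p = 0.171) and than in each sham library (exact p = 0.10, also the smallest possible; adjusted p = 0.14). The difference between 5 h and sham was -9.37 percentage points (exact p = 0.0571, adjusted p = 0.267). No class passed the adjustment in any comparison or in these repeats. Dissociation can set such shares, and unnamed clusters held 6.12% of cells in sham, 8.13% at 5 h and 14.9% at 24 h. Shares of kept cells also depend on one another. Among cells outside the lineage, microglia-like cells made up 20.9% in sham and 21.1% at 24 h. Astrocyte-like cells there went from 6.37% to 15.1%, and border macrophage or monocyte-like cells from 1.69% to 9.85%.

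**Figure D2:**
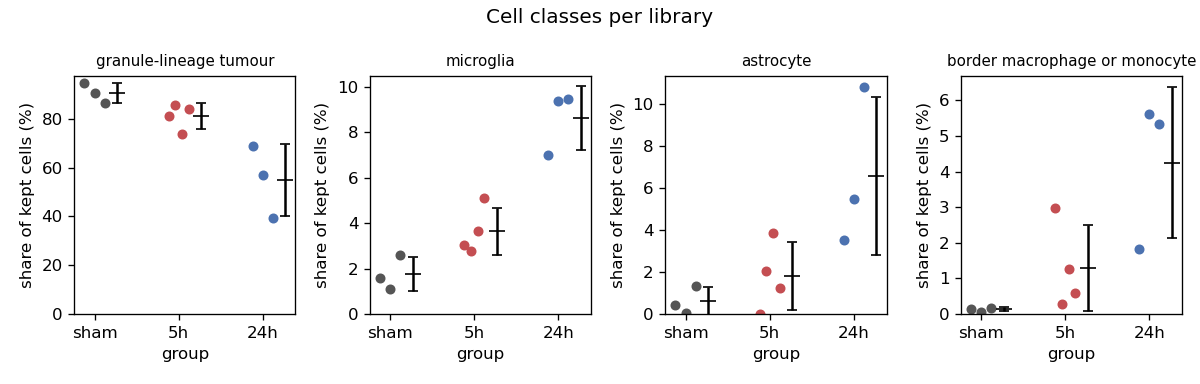
Share of kept cells (percent, vertical axis) of 4 cell classes in sham, 5 h and 24 h tumours. Points are libraries and bars beside them are mean ± SD (n = 3, 4 and 3); the granule-lineage share averaged 90.5% in sham and 55.0% at 24 h, microglia-like cells were at 1.77% and 8.62%, and no difference passed the adjusted test.

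At 5 h after irradiation, granule-lineage cells showed higher p53 target genes and neuronal differentiation genes, and lower DNA replication genes and hedgehog pathway genes, than in sham tumours. In the exon-counting libraries none of these list calls held with an estimated correlation. Cdkn1a, which encodes the cell cycle inhibitor p21, rose by 3.58 ± 0.21 on the log2 scale (SE, adjusted p = 0.000318), from 53.3 ± 4.26 CPM (SD, n = 2) to 635 ± 159 (n = 3). Atoh1 fell by 2.47 ± 0.31 (adjusted p = 0.00283), from 236 to 42.6 CPM. Neurod1, a transcription factor of granule neuron differentiation, rose by 1.19 ± 0.16 (adjusted p = 0.00345), from 490 to 1120 CPM. Across 15027 genes, 1684 rose and 1702 fell, and 832 of the former and 380 of the latter changed more than 2-fold. Without sham A1 the test called 986 genes, without sham B2 1175, without 5 h B2 2236 and without 5 h C2 2028. With the letter of the library code as a block, a fit with few residual degrees of freedom, it called 0. The planned fit of all 10 libraries (14789 genes) called 1 gene, Cdkn1a (log2 3.85 ± 0.29, adjusted p = 0.0058), and called 0 without sham A1 or sham B2 and 5 without 5 h A4. It called 9 gene lists, among them p53 targets (median 1.70, camera adjusted p = 9.97e-18), S phase (-0.62, camera adjusted p = 1.30e-13) and NF-kB genes (2.63, camera adjusted p = 9.81e-12), and 5 with an estimated correlation: NF-kB genes (adjusted p = 0.00944 with an estimated correlation) and the p53, S phase, differentiation and hypoxia lists (0.0491 each).

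Of 30 tested p53 targets, 21 rose at 5 h and 27 did when adjusted over the list alone. Their median log2 change was 1.60 (camera adjusted p = 1.11e-24, adjusted p = 0.214 with an estimated correlation). They included Ccng1 (2.40 ± 0.28, adjusted p = 0.00228), Dcxr (2.81 ± 0.23, adjusted p = 0.000832) and Bax, a pore-forming apoptosis protein (1.03 ± 0.11, adjusted p = 0.00198, from 266 to 545 CPM). Mdm2, the ubiquitin ligase that restrains p53, was at 62.0 CPM in sham and 74.4 at 5 h (log2 0.26 ± 0.12, adjusted p = 0.147). Of 18 apoptosis genes, 3 rose and 3 fell (median -0.11, camera adjusted p = 0.499), among them Bak1, which fell by 0.98 ± 0.12 (adjusted p = 0.00255), and Aifm1, which fell by 0.74 ± 0.09. The largest increases in abundant genes also took in Zc3h6 (2.39 ± 0.22), Klhl33 (2.23 ± 0.22) and Timp3, an inhibitor of matrix metalloproteinases (2.07 ± 0.23, adjusted p = 0.00203).

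Genes of S phase and of the hedgehog pathway were lower at 5 h. Of 42 S-phase genes, 26 fell, and 31 did when adjusted over the list alone (median -0.61, camera adjusted p = 4.34e-15, adjusted p = 0.379 with an estimated correlation). Cdca7 fell by 1.43 ± 0.15 (adjusted p = 0.00156) and Gins2, a part of the replicative helicase, by 0.93 ± 0.12 (adjusted p = 0.00297). Of 16 hedgehog genes, 7 fell, and 8 did when adjusted over the list alone (median -0.71, camera adjusted p = 3.87e-05, adjusted p = 0.318 with an estimated correlation). Smo fell by 0.58 ± 0.09 (adjusted p = 0.00463). Gli1, the transcription factor and transcriptional target of the pathway, fell by 1.27 ± 0.35 (adjusted p = 0.0345), from 32.8 to 13.6 CPM, and was not called without sham A1 (adjusted p = 0.0974), sham B2 (0.147) or 5 h B2 (0.064). Of 27 DNA repair genes 5 fell, 7 when adjusted over the list alone (median -0.29, camera adjusted p = 0.00506, adjusted p = 0.611 with an estimated correlation), including the checkpoint kinase Chek1 (log2 -1.09 ± 0.11). In contrast, genes of G2 and M phase had a median of -0.07 (2 of 53 rose and 2 fell, camera adjusted p = 0.625). The proliferation marker Mki67 was at 316 CPM in sham and 311 at 5 h (log2 -0.02 ± 0.09, adjusted p = 0.874), and Ccnb1, the mitotic cyclin, at 152 and 178 (0.22, adjusted p = 0.509). The signs of both are open, since Mki67 was at 0.03 without sham A1 and 0.02 without 5 h B2, and Ccnb1 at -0.01 without 5 h C1.

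Neuronal genes rose at 5 h. Of 22 granule neuron differentiation genes 14 rose, also 14 when adjusted over the list alone (median 0.92, camera adjusted p = 2.74e-10, adjusted p = 0.0933 with an estimated correlation). They included Grin2b, an NMDA receptor subunit (1.505 ± 0.09, adjusted p = 0.000363, from 27.5 to 77.9 CPM), the synaptic fusion protein Snap25 (1.01 ± 0.12) and Dcx, a microtubule protein of migrating neurons (0.94 ± 0.12, adjusted p = 0.00305). Among the largest decreases were the transcription factors Tlx3 (log2 -2.19 ± 0.18, from 241 to 52.6 CPM) and Hey1, a Notch target (-1.99 ± 0.10, adjusted p = 0.000234, from 219 to 55.1 CPM). Of 14 hypoxia and glycolysis genes 7 fell, 10 when adjusted over the list alone (median -0.87, camera adjusted p = 1.72e-05, adjusted p = 0.318 with an estimated correlation), including Vegfa (-1.92 ± 0.26) and P4ha1 (-1.28 ± 0.12, adjusted p = 0.00136). The chemokine receptor gene Cxcr4 fell by 1.43 ± 0.33 (adjusted p = 0.0178), from 72.8 to 27 CPM, and was not called without sham B2 (adjusted p = 0.131). It belongs to a list of 24 tested migration and matrix genes, of which 2 rose and 2 fell (camera adjusted p = 0.998). Granule-lineage cells of the groups lay mostly in different clusters: 2, 0, 8, 10, 15 and 19 in sham, and 1, 3, 7 and 11 at 5 h, with 0 and 6 in library C1. The 24 h libraries were themselves apart: A3 lay mostly in 0 and 6 (1598 and 1678 of 4875 cells), and B1 and D3 mostly in 16, 20 and 21 (1867, 1178 and 883 of 4930 cells in B1), with 25 and 22 cells of B1 in 0 and 6. Sham A1 and B2 also differed, with 4912 cells of A1 in cluster 2 and 2551 of B2 in cluster 10.

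Inflammatory genes were also higher in the 5 h sums, at low levels. Of 18 NF-kB and cytokine genes, 10 rose, and 13 did when adjusted over the list alone (median 2.18, camera adjusted p = 2.79e-05, adjusted p = 0.214 with an estimated correlation). Cd83 rose by 2.21 ± 0.37 (adjusted p = 0.00617), from 0.577 to 2.67 CPM, and was not called without sham A1 (adjusted p = 0.05). Ccl2, a monocyte-attracting chemokine, was at 0.387 CPM in sham and 2.13 at 5 h (log2 2.47 ± 0.82, adjusted p = 0.0612), and was called without sham B2 (4.31, adjusted p = 0.0442). Of 11 antigen presentation genes 4 rose (median 1.07, camera adjusted p = 0.0163, adjusted p = 0.678 with an estimated correlation), a call that was lost without sham B2 (camera adjusted p = 0.290). When adjusted over the list alone 5 rose and 1 fell. Markers of other cell types moved with these genes. The neutrophil marker S100a8 rose from 0.0306 to 1.58 CPM and was not called without sham A1 (adjusted p = 0.137) or sham B2 (0.111). Endothelial markers had a median of 1.22 (4 of 7 rose, camera adjusted p = 0.123), a list that the planned fit of all 10 libraries called (median 1.45, camera adjusted p = 0.00596, adjusted p = 0.299 with an estimated correlation), microglia markers 0.85 (0 of 11 called, camera adjusted p = 0.123) and oligodendrocyte markers 1.11 (3 of 8 rose, camera adjusted p = 0.0622). Oligodendrocyte progenitor markers had a median of -1.34 (3 of 5 fell, camera adjusted p = 0.0520), and interferon genes one of 0.45 (1 of 22 rose, camera adjusted p = 0.419). The member C1ql1 of the progenitor list was also a leading gene of granule-lineage clusters 2, 10 and 11. The calls on these marker lists were not stable: endothelial markers were called without 24 h A3 (camera adjusted p = 0.0226) or 24 h B1 (0.0159), microglia markers without 24 h D3 (0.0316) or 5 h C1 (0.0385), oligodendrocyte markers without 24 h D3 (0.0458) or 5 h B2 (0.0295), and progenitor markers without 24 h A3 (0.0108), 24 h B1 (0.00874), 24 h D3 (0.0247) or 5 h C2 (0.0368).

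**Figure D3:**
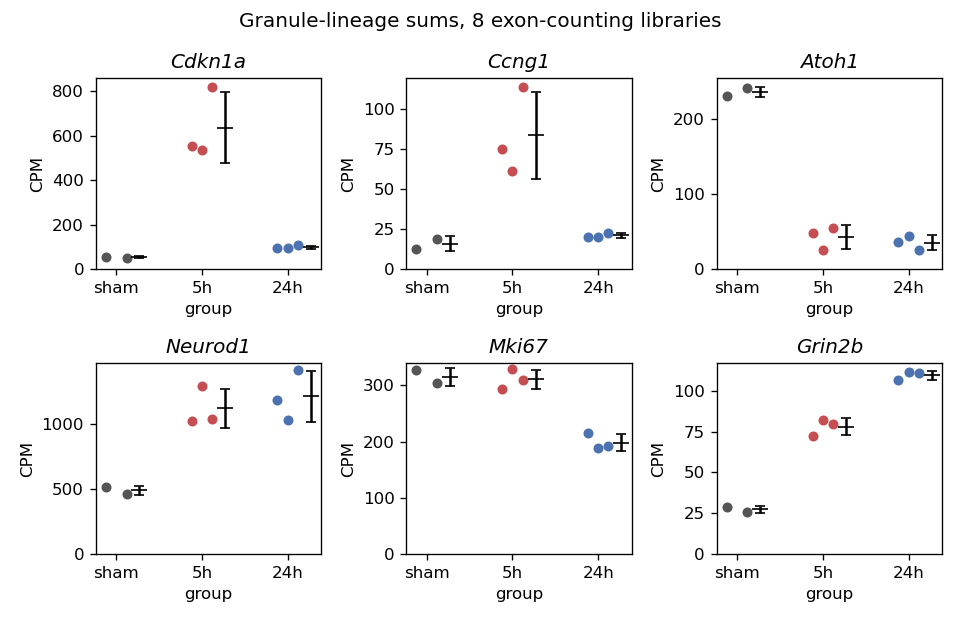
Level (CPM, vertical axes) of 6 genes in granule-lineage sums of the 8 exon-counting libraries by group, with a point per library and mean ± SD beside the points (n = 2, 3 and 3). Cdkn1a averaged 53.3, 635 and 98.9 CPM in sham, 5 h and 24 h, while Atoh1 was lower and Neurod1 higher than sham at both times, and Mki67 fell from 316 CPM in sham to 198 at 24 h.

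At 24 h, the sums of granule-lineage cells had lower hedgehog and mitotic genes, and higher differentiation and interferon-responsive genes, than in sham. In the exon-counting libraries only the call on the differentiation list held with an estimated correlation. Mki67 fell by 0.67 ± 0.09 (adjusted p = 0.00321), to 198 CPM. Grin2b rose by 1.995 ± 0.09 (adjusted p = 8.4e-05), to 110 CPM, and Neurod1 by 1.31 ± 0.16 (adjusted p = 0.00247), to 1212 CPM. Atoh1 fell by 2.72 ± 0.32 (adjusted p = 0.00207), to 35.3 CPM. Of 15027 genes, 1567 rose and 1677 fell, 822 and 523 of them more than 2-fold. Without sham A1 the test called 993 genes, without sham B2 1276, with the letter of the library code as a block 466, and 987 without both 24 h B1 and 24 h D3, a fit in which the lone 24 h library was assumed to vary like the other groups. The planned fit of all 10 libraries called 9 genes, 8 higher and 1 lower, with adjusted p values from 0.0456 to 0.0473. It called 0 genes without sham A1, sham B2, 5 h B2, 5 h C1, 5 h C2 or any 1 of the 24 h libraries, 1 without sham A5, and 44 without 5 h A4. It called 15 gene lists, 0 of them with an estimated correlation.

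Genes of the mature neuron rose at 24 h. Of 22 differentiation genes 14 rose, 16 when adjusted over the list alone (median 1.06, camera adjusted p = 2.68e-15), and this call held with an estimated correlation (adjusted p = 0.0308 with an estimated correlation). Mapt, which encodes the axonal protein tau, rose by 1.52 ± 0.13 (adjusted p = 0.000617), from 87.9 to 251 CPM. Of 8 mature granule neuron markers 4 rose, 5 when adjusted over the list alone (median 1.25, camera adjusted p = 7.80e-05, adjusted p = 0.116 with an estimated correlation). Among the largest increases were Sez6 (2.47 ± 0.18, adjusted p = 0.000389, from 9.21 to 51.1 CPM), the adhesion genes Cntn1 (2.46 ± 0.34) and Pcdh9 (2.45 ± 0.37), and the synaptic vesicle gene Sv2a (2.24 ± 0.24). Of these, Sez6 was also called with all 10 libraries (adjusted p = 0.0472).

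Some proliferation genes and most hedgehog genes were called lower at 24 h. Of 53 genes of G2 and M phase 19 fell, 27 when adjusted over the list alone (median -0.42, camera adjusted p = 7.05e-10, adjusted p = 0.396 with an estimated correlation), including the mitotic kinesin Kif11 (log2 -0.91 ± 0.12, from 130 to 69.4 CPM). Of 42 S-phase genes 13 fell, 21 when adjusted over the list alone (median -0.44, camera adjusted p = 4.80e-08, adjusted p = 0.405 with an estimated correlation). Of 27 DNA repair genes 13 fell (median -0.42, camera adjusted p = 1.69e-05, adjusted p = 0.379 with an estimated correlation), and adjusted over the list alone 18 fell and 1 rose. Of 16 hedgehog genes 10 fell, 13 when adjusted over the list alone (median -1.32, camera adjusted p = 1.67e-10, adjusted p = 0.173 with an estimated correlation). Mycn, a proto-oncogene that drives progenitor growth, fell by 1.54 ± 0.18 (adjusted p = 0.00190), from 329 to 113 CPM, and Sfrp1 by 1.77 ± 0.16 (adjusted p = 0.000820), from 1144 to 335 CPM. Gli1 fell by 1.28 ± 0.36 (adjusted p = 0.0372), a call lost without any 1 of sham A1 (adjusted p = 0.104), sham B2 (0.152), 5 h B2 (0.0561), 24 h A3 (0.0928), 24 h B1 (0.0963) and 24 h D3 (0.0545). Ccnb1 was at 130 CPM (-0.23, adjusted p = 0.521). Rbp4 (-2.74 ± 0.13, from 77.5 to 11.6 CPM) and Srebf1, a regulator of lipid synthesis (-2.33 ± 0.21, from 99.1 to 19.9 CPM), were among the largest decreases. Of 14 hypoxia genes 6 fell, also 6 when adjusted over the list alone (median -0.69, camera adjusted p = 0.00271, adjusted p = 0.396 with an estimated correlation), a call lost without sham B2 (camera adjusted p = 0.0882).

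Migration and matrix genes went both ways at 24 h. Of 24 tested members 3 rose and 7 fell, 4 and 7 when adjusted over the list alone (median -0.22, camera adjusted p = 0.217). Spp1, a secreted matrix protein also abundant in microglia-like cells, rose by 4.12 ± 0.67 (adjusted p = 0.00588), from 1.16 CPM to 19.9 ± 16.5, and Cxcr4 fell by 1.93 ± 0.33 (adjusted p = 0.00677), to 19.0 CPM.

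The p53 targets had a median of 0.16 at 24 h. Of 30, 5 rose, also 5 when adjusted over the list alone. In the exon-counting libraries the list was not called (camera adjusted p = 0.0590). The planned fit of all 10 libraries called it as higher (median 0.36, camera adjusted p = 0.0153, adjusted p = 0.430 with an estimated correlation), and so did the exon-counting libraries without 24 h A3 (camera adjusted p = 0.0491), 5 h C2 (0.0310) or sham B2 (0.00747). Cdkn1a rose by 0.89 ± 0.18 (adjusted p = 0.0129), to 98.9 ± 6.88 CPM, and was not called without sham A1 (adjusted p = 0.0637) or sham B2 (0.0858). Ccng1 was at 21 CPM (0.40, adjusted p = 0.308), Mdm2 at 57.5 CPM (-0.11, adjusted p = 0.542), Bax at 325 CPM (0.29, adjusted p = 0.0969, called without 5 h C1 with adjusted p = 0.0353) and Ccl2 at 1.43 CPM (1.98, adjusted p = 0.116).

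Of 22 interferon-responsive genes, 17 rose at 24 h, 19 when adjusted over the list alone (median 3.41, camera adjusted p = 1.65e-07, adjusted p = 0.400 with an estimated correlation). Bst2, which tethers enveloped virus to the cell surface, rose by 3.66 ± 0.61 (adjusted p = 0.00600), from 1.29 CPM to 16.4 ± 10.2. The 24 h libraries differed widely: Ifit1, chosen after its values were seen, was at 0.46 CPM in A3, 11 in B1 and 5.15 in D3, against 0.13 and 0.16 in sham. Without B1 the median was 2.27 and 6 members rose, without D3 3.17 and 6, without 5 h B2 or 5 h C2 14 rose, and without sham A1 or sham B2 1 rose. Sex-linked transcripts, also chosen after their values were seen, divided the same libraries: Ddx3y, a Y-linked gene, was at 0 in 24 h B1 and D3 and at 49 to 69 CPM in the other exon-counting libraries. Xist, the transcript that silences an X chromosome in females, was at 1369 CPM in B1, 0.90 in D3 and at most 0.13 in the others. In the cells of D3 outside the lineage Xist was at 368 CPM. Sham A5 lacked Ddx3y too and had Xist at 895 CPM. All exon-counting libraries without Ddx3y were thus at 24 h, so that for interferon genes the difference between the times and that between animals with and without Y-linked RNA overlap. Without both B1 and D3, with A3 as the lone 24 h library, the interferon median was 0.95 against sham. Border macrophage or monocyte-like cells also made up more of the kept cells in B1 (5.62%) and D3 (5.33%) than in A3 (1.82%). The part of the interferon levels due to RNA of other cells was not measured.

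Markers of other cells also moved at 24 h. Border macrophage or monocyte markers had a median of 1.67 (3 of 5 rose, 4 when adjusted over the list alone, camera adjusted p = 0.00255, adjusted p = 0.213 with an estimated correlation) and microglia markers one of 1.59 (2 of 11 rose, 9 when adjusted over the list alone, camera adjusted p = 0.00295, adjusted p = 0.472 with an estimated correlation). The microglial gene Tyrobp, chosen after its values were seen, was at 13.6 CPM in A3, 15.4 in B1 and 3.09 in D3, against 3.34 and 3.17 in sham. Erythrocyte markers had a median of 2.11 (0 of 5 called by edgeR, camera adjusted p = 0.0421, adjusted p = 0.472 with an estimated correlation), a call lost without sham A1 (camera adjusted p = 0.202), 5 h C1 (0.0545), 24 h B1 (0.0683) or 24 h D3 (0.0672), and not made with all 10 libraries (0.0934). Alongside them, 6 of 11 antigen presentation genes rose, 7 when adjusted over the list alone (median 1.85, camera adjusted p = 0.000749, adjusted p = 0.400 with an estimated correlation), and 5 of 18 NF-kB genes, also 5 adjusted over the list alone (median 1.49, camera adjusted p = 0.00718, adjusted p = 0.379 with an estimated correlation). Of 12 reactive astrocyte genes 7 rose and 1 fell, 8 and 1 when adjusted over the list alone (median 1.66, camera adjusted p = 0.00889, adjusted p = 0.400 with an estimated correlation), a call lost without 24 h B1 (camera adjusted p = 0.0832). Of 18 immediate early genes 3 rose, 2 when adjusted over the list alone (median 0.46, camera adjusted p = 0.00695, adjusted p = 0.379 with an estimated correlation), and Fos rose by 1.84 ± 0.33, a call lost without sham B2 (adjusted p = 0.0538). Oligodendrocyte progenitor markers went the other way, with 4 of 5 lower, also 4 when adjusted over the list alone (median -1.70, camera adjusted p = 4.38e-06, adjusted p = 0.116 with an estimated correlation), among them Olig1 (log2 -3.24 ± 0.43), but with all 10 libraries the list was not called (camera adjusted p = 0.134). This list is not confined to other cells, since its member C1ql1 was among the 10 leading genes of granule-lineage clusters 2, 10 and 11. Of 12 astrocyte markers 3 rose and 3 fell, the same when adjusted over the list alone (median 0.052, camera adjusted p = 0.538), with S100b among the lower (log2 -4.11 ± 0.64).

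Between 5 h and 24 h, p53 targets fell in granule-lineage cells. Interferon genes rose in the sums of these cells, mainly in the 24 h libraries B1 and D3, which lacked Ddx3y. Neither list call held with an estimated correlation. Cdkn1a fell by 2.68 ± 0.17 (adjusted p = 0.00188), Ccng1 fell by 1.999 ± 0.24 (adjusted p = 0.00988), and Zmat3 and Trp53inp1, both p53 targets, fell by 1.62 ± 0.18 and 1.61 ± 0.19 (adjusted p = 0.00813 and 0.00905). In all, 482 genes rose and 537 fell, 110 and 182 of them more than 2-fold. Leaving out 1 library moved this count strongly, to 553 without sham A1, 557 without sham B2, 79 without 5 h B2, 42 without 5 h C2, 672 without 24 h A3, 103 without 24 h B1 and 95 without 24 h D3. It was 0 with the letter of the library code as a block, and 0 without both 24 h B1 and 24 h D3, under the same assumption. The planned fit of all 10 libraries called 2 genes, both lower: Cdkn1a (log2 -2.79 ± 0.27, adjusted p = 0.0428) and 9530053A07Rik (adjusted p = 0.0428), the latter outside the naming rule and chosen after its values were seen. It called 0 genes without any 1 library other than sham A5, at 698 genes with an unadjusted p under 0.05 over all 10. It called 12 gene lists, 6 without 5 h B2 and 5 without 5 h C1, and 0 with an estimated correlation.

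Of 30 p53 targets, 20 fell between 5 h and 24 h (median -1.39, camera adjusted p = 1.00e-36, adjusted p = 0.222 with an estimated correlation), and adjusted over the list alone 22 fell and 1 rose. Of 53 genes of G2 and M phase 13 fell, 29 when adjusted over the list alone (median -0.41, camera adjusted p = 3.31e-16, adjusted p = 0.305 with an estimated correlation). Of 22 interferon genes 9 rose (median 2.86, camera adjusted p = 2.16e-11, adjusted p = 0.305 with an estimated correlation), and adjusted over the list alone 20 rose and 1 fell. Of these members 0 were called without 24 h B1, 24 h D3, 5 h B2 or 5 h C2. In A3, the lone 24 h library without B1 and D3, the median against 5 h was 0.27 for interferon genes and -1.44 for p53 targets. S-phase genes had a median of 0.12 with 5 of 42 higher and 1 lower, 7 and 1 when adjusted over the list alone (camera adjusted p = 0.00258, adjusted p = 0.610 with an estimated correlation), a call lost without 5 h C1 (camera adjusted p = 0.523). Hedgehog genes had a median of -0.45, and 2 of 16 fell, also 2 adjusted over the list alone (camera adjusted p = 0.00158, adjusted p = 0.370 with an estimated correlation). With all 10 libraries this list was not called (median -0.15, camera adjusted p = 0.227). Erythrocyte markers had a median of 2.88 (0 of 5 called by edgeR, 5 when adjusted over the list alone, camera adjusted p = 0.000183, adjusted p = 0.305 with an estimated correlation), and with all 10 libraries one of -0.22, while their mean (0.69) and the camera test (adjusted p = 0.0296) pointed upward. Nectin3, a cell adhesion gene, rose by 1.47 ± 0.18 (adjusted p = 0.0101), from 40.3 to 112 CPM against 72 in sham, and was not called without 5 h C2 (adjusted p = 0.0507).

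Many genes were called in the same direction at both times. In the exon-counting libraries, 854 genes were higher and 898 lower than sham at both 5 h and 24 h, and 7 were called in opposite directions. Independent lists of these sizes would share 175.6 higher and 189.9 lower genes. Because both comparisons use the same sham libraries, unchanged groups were simulated, with every library, sham included, drawn from a common mean per gene. They shared 0.1 called genes on average over 20 draws. Hardly any gene is called where nothing changed, so this count could not measure what the shared sham adds to the overlap. The covariance of the fold changes was 0.575 against a simulated 0.0912, a difference of 0.483, and Pearson's r across genes, which are not independent replicates, was 0.731 against 0.575. The sham libraries were not split between these comparisons, so part of the excess over independent lists may come from the shared controls. In the planned fit of all 10 libraries no gene was shared (0 against 0 simulated; 1651 and 1824 genes had an unadjusted p under 0.05, and DESeq2 called 1078 and 1052), with a covariance of 0.557 against 0.448.

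The rise of Cdkn1a at 5 h was spread over many cells. After thinning to 1500 UMIs, 5.55% ± 0.39 of granule-lineage cells had a Cdkn1a UMI in sham (SD, n = 3), 52.5% ± 11.2 at 5 h (n = 4) and 9.83% ± 0.86 at 24 h (n = 3). The 5 h libraries ranged from 41.65% to 65.99% (exact permutation p = 0.0286 against each other group, adjusted p = 0.114), and 24 h exceeded sham in each library (exact p = 0.10, the smallest possible). Without thinning the shares were 6.79% to 23.19% in sham, 72.99% to 82.90% at 5 h and 30.99% to 35.92% at 24 h. Ccng1 was found in 1.99%, 10.0% and 2.77% of cells on average. Neurod1 was found in 30.7% ± 15.7, 65.8% ± 17.7 and 75.7% ± 1.63 of cells (exact p = 0.0857 for 5 h against sham), and Mki67 in 16.9% ± 3.86, 13.8% ± 4.63 and 11% ± 0.47. In microglia-like cells thinned alike, which should lack Neurod1 and Atoh1, Neurod1 was found in 9.69%, 9.34% and 5.55% of cells and Atoh1 in 3.1%, 0.718% and 0 of 1135 cells at 24 h, which allows a share of up to 0.264% of cells with a UMI, for counting error only and with the libraries pooled. Their median depth was 1807, 1881 and 2501 UMIs, against 7900, 6391 and 8318 in granule-lineage cells. Cdkn1a was itself found in 3.88%, 44.3% and 30.4% of microglia-like cells. Atoh1 was found in 15.1% ± 13.2, 3.11% ± 2.41 and 3.55% of granule-lineage cells, with sham A5 and 5 h A4 at 0.

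Microglia-like cells carried inflammatory genes at 5 h that were lower at 24 h. In the exon-counting libraries Il1b, an inflammatory cytokine, rose by 3.77 ± 0.61 at 5 h (adjusted p = 0.0341), from 133 to 1818 CPM, and fell by 4.47 ± 0.52 from there to 24 h (adjusted p = 0.00252), to 81.9 CPM. The endotoxin co-receptor Cd14 rose by 4.95 ± 0.72 (adjusted p = 0.0191) and Cdkn1a by 4.25 ± 0.59 (adjusted p = 0.0191), from 35.1 to 666 CPM. At 24 h against sham, Spp1, which encodes osteopontin, rose by 4.38 ± 0.82 (adjusted p = 0.0227), from 557 to 11621 CPM, and P2ry12, a receptor of resting microglia, fell by 2.27 ± 0.35 (adjusted p = 0.0116), from 217 to 45.2 CPM. Hmox1, which degrades heme, rose by 2.63 ± 0.43 between 5 h and 24 h (adjusted p = 0.00900). Of 17 NF-kB genes 5 rose at 5 h, 17 when adjusted over the list alone (median 1.74, camera adjusted p = 1.01e-25, adjusted p = 0.0284 with an estimated correlation), and of 24 p53 targets 3 rose, while adjusted over the list alone 13 rose and 1 fell (median 1.02, camera adjusted p = 6.96e-13, adjusted p = 0.0284 with an estimated correlation). Between 5 h and 24 h, 9 of 17 NF-kB genes fell, 14 when adjusted over the list alone (median -1.16, camera adjusted p = 1.19e-16, adjusted p = 0.0881 with an estimated correlation). At 24 h 4 of 23 interferon genes rose against sham, 15 when adjusted over the list alone (median 2.999, camera adjusted p = 2.43e-17, adjusted p = 0.174 with an estimated correlation). The 24 h libraries were again A3, B1 and D3, of which B1 and D3 lacked Ddx3y in granule-lineage cells. The overlap stated there between time and lack of Y-linked RNA thus applies to these interferon genes too. In the exon-counting libraries the class lay in clusters 13 and 31, with median depths of 1879 and 20101.5 UMIs. Cluster 31 held 22 of 207 and 11 of 206 cells in sham A1 and B2. At 5 h it held 22 of 308 (B2), 37 of 232 (C1) and 104 of 557 (C2). At 24 h it held 26 of 497 (A3), 180 of 815 (B1) and 14 of 151 (D3). A change in the mix of cells within the class was not tested.

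The test in microglia-like cells of the exon-counting libraries (7739 genes) called 36 higher and 5 lower genes at 5 h against sham, 84 and 79 at 24 h against sham, and 143 and 225 between the times. The first total, 41, became 0 without sham A1 or sham B2, 8 without 5 h B2, 15 without 5 h C1, 78 without 5 h C2, 164 without 24 h A3 and 21 without 24 h D3. The second, 163, became 6 without sham A1, 1 without sham B2, 105 without 5 h B2, 656 without 24 h A3, 65 without 24 h B1 and 73 without 24 h D3. The third, 368, ranged from 102 without 5 h C2 to 648 without 24 h A3, with 175 without sham A1, 175 without sham B2, 105 without 5 h B2, 244 without 5 h C1, 173 without 24 h B1 and 150 without 24 h D3. With all 10 libraries (7198 genes), edgeR called 0 genes in each microglia comparison, with 501, 453 and 579 genes at an unadjusted p under 0.05, and DESeq2 called 115, 124 and 159.

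Other classes were compared mainly between 5 h and 24 h. Border macrophage or monocyte-like cells of the exon-counting libraries had 310 higher and 328 lower genes at 24 h (7070 genes). Ms4a7, a border macrophage marker, rose by 4.34 ± 0.68 (adjusted p = 0.00913), from 16.2 to 368 CPM, and the dendritic cell migration receptor Ccr7 fell by 2.72 ± 0.70 (adjusted p = 0.0441), from 1025 to 158 CPM. Of 8 border macrophage markers 7 rose, also 7 when adjusted over the list alone (median 1.49, camera adjusted p = 4.00e-10, adjusted p = 0.0472 with an estimated correlation). This list also served to name the class, and a change in the mix of cells within the class was not tested. The total, 638, was 191 without 5 h B2, 291 without 5 h C1, 305 without 5 h C2, 275 without 24 h B1 and 322 without 24 h D3. With all 10 libraries edgeR called 0 genes (884 at an unadjusted p under 0.05; 583 with DESeq2), and 638 without 5 h A4. Astrocyte-like cells had 11 higher and 2 lower genes at 5 h against sham, 30 and 77 at 24 h against sham, and 81 and 217 at 24 h against 5 h (10883 genes). In these cells Fas, a p53-regulated death receptor, rose by 3.06 ± 0.41 at 5 h (adjusted p = 0.0417), from 11.6 to 99.5 CPM, Sox2 fell by 1.53 ± 0.22 (adjusted p = 0.0439), and the neutrophil-attracting chemokine Cxcl1 fell by 3.66 ± 0.41 between 5 h and 24 h (adjusted p = 0.00443), from 2521 to 199 CPM.

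The astrocyte counts depended on single libraries. The count of 13 at 5 h became 0 without sham A1, sham B2, 5 h B2 or 24 h B1, 6 without 5 h C1 and 30 without 24 h A3. The count of 107 became 13 without sham A1, 1 without sham B2, 23 without 5 h B2, 60 without 5 h C2, 330 without 24 h A3, 39 without 24 h B1 and 52 without 24 h D3. The count of 298 became 65 without 5 h B2, 163 without sham A1, 166 without sham B2 or 24 h D3, 191 without 5 h C1, 162 without 5 h C2 and 185 without 24 h B1. In oligodendrocyte progenitor-like cells, 58 genes rose and 109 fell between 5 h and 24 h (8501 genes). These cells lay in different clusters at the 2 times: at 5 h, 72 of 91 (B2), 71 of 79 (C1) and 58 of 76 (C2) were in c26.0, while at 24 h 78 of 89 in B1 were in c26.2 and 28 of 31 in A3 in c26.3. In them Ccl2 fell by 5.73 ± 0.58 (adjusted p = 0.000583), from 1118 to 14.2 CPM. This count of 167 was 12 without 5 h B2. In endothelial-like cells 29 genes rose and 157 fell (7641 genes). Csf3, which encodes a growth factor of neutrophils, fell by 8.02 ± 0.68 (adjusted p = 0.000864), from 204 to 0.380 CPM. The latter level is near the floor in the 24 h sums (57 cells in B1 and 37 in D3), so the size of this fall is uncertain. The count of 186 in endothelial-like cells was 24 without 5 h B2, 481 without 5 h C1, 5 without 24 h B1 and 68 without 24 h D3. Mural markers also fell in these cells, with a median of -2.60. They too lay in different clusters: at 5 h c29.3 and c29.4 held 26 and 13 of 57 cells in B2, 13 and 17 of 38 in C1 and 22 and 26 of 55 in C2, and at 24 h c29.0 held 45 of 57 in B1 and 25 of 37 in D3. Both 24 h libraries of this comparison lacked Ddx3y, and all 5 h libraries had it. Mature granule neuron-like cells had 0 genes called by edgeR (117 of 2716 genes at an unadjusted p under 0.05; 1 with DESeq2), 1 without 5 h C1 and 3 without 24 h A3. Oligodendrocyte-like and mural-like cells were too few for a comparison.

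In mm10 (GENCODE vM21), Cdkn1a (ENSMUSG00000023067) lies on chromosome 17 from 29090976 to 29100727, Mdm2 (ENSMUSG00000020184) on chromosome 10 from 117688875 to 117710758, Ccng1 on chromosome 11 from 40748552 to 40755311 and Bax on chromosome 7 from 45461697 to 45466898. Mki67 lies on chromosome 7 from 135689784 to 135716361, Ccnb1 on chromosome 13 from 100778650 to 100786570, and Gli1 (ENSMUSG00000025407) on chromosome 10 from 127329882 to 127341974. Neurod1 (ENSMUSG00000034701) lies on chromosome 2 from 79452521 to 79456751, Atoh1 (ENSMUSG00000073043) on chromosome 6 from 64729125 to 64731245, and Ccl2 on chromosome 11 from 82035571 to 82037453. The values of each are the deposited counts of the gene, and the positions are those of the whole gene.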

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

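The tests of intron counting, of low depth, of a loss of granule-lineage cells alone and of RNA mixed in from other cells, and the regroupings of granule-lineage libraries, were chosen only after the result was seen.

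In sham A5 and 5 h A4, single-exon genes were at 0 counts. Counting of reads in introns predicts that most single-exon genes lack counts and that genes with short introns lie below genes with long ones. At least 79.375% of these genes were at 0 in each of the 2 libraries, and genes with the longest introns lay above those with the shortest by 2.47 (sham A5) and 2.26 (5 h A4) on the log2 scale. Depth alone would leave at most 6.839e-37 of the 160 genes at 0, which argues against low depth. These values are what intron counting predicts in that pair, which spans the sham and 5 h groups. No biological explanation was tested, and neither was a difference in how the libraries were made, although their barcodes also differed from the rest.

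The share of granule-lineage cells was lower at 24 h than in sham. A loss of these cells alone would raise all other classes alike, but their shares outside the lineage moved apart by 2.51965 on the log2 scale, from 0.02 for microglia-like to 2.54 for border macrophage or monocyte-like cells, the latter resting on 38 cells in sham; the log2 ratio of these 2 classes was at most -3.37 in each sham library and at least -1.95 in each 24 h library. This rests on how clusters were named. With unnamed clusters 23, 26.1, 35 and 37 given the class of their highest list, the shares moved apart by 2.82. Other unnamed clusters, such as 9 and 22, kept no class. With cluster 23, whose leading markers tie, counted as border macrophages the shares moved apart by 1.24. This is under the limit of 2 for an exclusion, which was written after the shares were seen. The log2 ratio was then at most -0.823 in sham and at least -0.539 at 24 h. A loss of these cells alone thus stays open. The cell filter and doublet removal were argued against, since the difference was -38.644 percentage points over every deposited barcode and -35.4786 over kept cells. With unnamed granule-marker clusters counted in the lineage, it was -28.1963 points, 0.795 of the kept value. Radiation, dissociation and sampling of the tissue stay open, and entry of border macrophages or monocytes may be part of the change.

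Atoh1 was lower at 5 h than in sham in the exon-counting libraries. Fewer cycling cells were argued against as the whole cause, since among cells with at least 2 UMIs of Mki67 and Top2a the log2 ratio was -1.8366, against -2.39861 over all granule-lineage cells. RNA of other cells would lower all granule-lineage markers, but the 9 markers outside the hedgehog list had a median log2 change of 0.5187. A response to radiation may remain, as a hypothesis, with 2 sham libraries behind it. A shift between tumour cell states present before irradiation was not tested.

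Regrouping the libraries asked whether chance gives as many genes. For 5 h against sham in all 10 libraries, chance could not be excluded: 2 of 35 splits gave the real count of 1, the highest other being 1, in the split that placed 5 h A4 with the 3 sham libraries. For 24 h against 5 h in all 10 libraries, 1 of 35 splits, the real one, gave 2 genes and the highest other gave 0. That share, 0.0286, was under 0.05, but it is the smallest that 35 splits can give and was not adjusted for the number of regroupings. As the count was 2 genes, and 0 without any 1 library other than sham A5, chance is not taken as excluded. For the remaining comparisons the 10 splits were too few for a share under 0.05: 24 h against sham gave 9 genes in the real split and 3 in the highest other, and 24 h against 5 h gave 1019 and 1 in exon-counting granule-lineage cells, 298 and 0 in astrocyte-like cells, 368 and 5 in microglia-like cells, and 638 and 0 in border macrophage or monocyte-like cells.

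In 5 of 36 groups of 4 libraries at 5 h, 1 library lay far from the others, where chance gives about 1 in 20. The gap divided by the range was 0.991619 for the neutrophil-like share (C1 high), 0.838074 for the endothelial-like share (A4 low, at 0 cells, since 12 of its cells lay in the unnamed cluster 37; with them A4 was at 0.650%, the gap was 0.345 of the range and A4 was not apart), 0.865767 for the mural-like share (A4 high, at 0.705%), 0.900227 for the share of cells with an Mki67 UMI (A4 low) and 0.875996 for the Mki67 level (A4 low, at 51.7 CPM). Of the 4 that do not come from naming, the library apart was A4 in 3, 1 of the pair in which single-exon genes were at 0.

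Of the 15 lists that differed between 24 h and 5 h by direct test at the preset correlation, 13 were also called against sham at 1 or both times. With an estimated correlation 0 of the 13 differed (adjusted p from 0.222 to 0.610). They are given here as the median log2 difference of 24 h from 5 h. Those above 0 were mature granule neuron markers at 0.637575, border macrophage markers at 1.2923, erythrocyte markers at 2.8848, S phase at 0.115555, differentiation at 0.255453, interferon at 2.85917, immediate early genes at 0.355862 and reactive astrocyte genes at 0.635039. Those below 0 were oligodendrocyte progenitor markers at -0.983342, p53 targets at -1.39336, G2 and M phase at -0.414397, hedgehog at -0.452082 and NF-kB at -0.512099. At the preset correlation, the test was lost for S phase without 5 h C1 (camera adjusted p = 0.523), for reactive astrocyte genes without 24 h B1 (0.0684), for differentiation without 24 h A3 (0.0731) or 5 h B2 (0.0560), and for NF-kB without 24 h A3 (0.113). The planned fit of all 10 libraries did not call hedgehog (camera adjusted p = 0.227), differentiation (0.113) or oligodendrocyte progenitor markers (0.129).

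Single genes of the granule lineage also differed between the times by direct test. On the log2 scale, 24 h lay below 5 h for Cdkn1a (-2.685), Ccng1 (-1.999), Bax (-0.7469), Mki67 (-0.648), Zc3h6 (-1.528), Dcxr (-2.329), Ckap2 (-1.408), Tubb4b (-0.6806), Rbp4 (-0.9937), Sfrp1 (-0.9921), S100b (-2.815) and Kif11 (-0.778). It lay above 5 h for Gins2 (0.4742), Grin2b (0.4908), Aifm1 (0.4092), Cd63 (0.3587), Ifi27 (3.562), Sez6 (1.405), Cntn1 (1.25), Pcdh9 (1.244), Pcp4 (1.381), Pf4 (2.574), Plac8 (3.311), Mapt (0.5108), Bst2 (2.764), Oas1a (4.51) and Fos (1.751). Most of these 27 edgeR calls depended on single libraries: 8 were left without 5 h B2, 7 without 5 h C2, 8 without 24 h B1, 9 without 24 h D3, 20 without 24 h A3, 21 without sham A1 or sham B2, 25 without 5 h C1, and 0 without both 24 h B1 and 24 h D3. Cdkn1a, Ccng1, Ckap2, Dcxr, Zc3h6, Rbp4 and Sez6 were called with any 1 library left out, Bst2 in 4 of 8 such fits, Oas1a in 2 of 6, Aifm1 in 2 of 8, Cd63, Mapt and Pcdh9 in 1 of 8, and Gins2 in 0 of 8 (lowest adjusted p = 0.0512).

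In cells of unnamed clusters, which the sums per class leave out, Cdkn1a averaged 444.692 CPM at 5 h, against 12.1 and 23.0 CPM in the 2 exon-counting sham libraries and 133, 408 and 190 CPM at 24 h.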

How the results depend on the processing

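The addition of a covariate for library type, of unnamed granule-marker clusters, of class names for unnamed clusters, of a fit without both 24 h libraries that lack Ddx3y (B1 and D3), and of every repeat that starts from the 8 exon-counting libraries was chosen after seeing the data. No paired analysis was possible because the groups share fewer than 2 library codes. Over 193 comparisons of 138 named genes, 4395 repeats left 3773 calls as they were, weakened 596, strengthened 10 and turned the sign of 16. The letter of the code as a block ended 144 of them, with few residual degrees of freedom, leaving out sham A1 81, sham B2 72 and both 24 h B1 and D3 55. Where 1 library of a group was left, it was assumed to vary like the other groups. Depth limited sham A5, 5 h A4 and 24 h D3 most. Where no cause is named below, the cause was not tested.

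Granule-lineage counts are given in the order 5 h against sham, 24 h against sham and 24 h against 5 h. From all 10 libraries (1, 9 and 2 genes), RLE size factors gave 2, 1 and 0, DESeq2 1078, 1052 and 185, limma-voom 74, 77 and 1, the compared groups alone 0, 0 and 0, the letter block 0, 0 and 0, and the library type covariate 3899, 3012 and 598. Without sham A5 and 5 h A4 the counts were 3386, 3244 and 1019, and with their removal the dispersion (BCV) fell from 0.708 to 0.223. Genes shared between the covariate fit and the exon-counting libraries were 2889, 2752 and 586, all in the same direction. For 24 h against sham, no filter gave 0, stricter cells 0, all cells 624, unnamed clusters added 21 and thinned sums 0. For 24 h against 5 h, no filter gave 0, stricter cells 1, all cells 0 and thinned sums 0. For 5 h against sham, every barcode gave 2 and mature clusters added 14. Leaving out 1 library gave 0 to 5, 0 to 44 and 0 to 2. Of the lists (9, 15 and 12), an estimated correlation left 5, 0 and 0, fry called 5, 5 and 0, all cells gave 20 at 5 h, and leaving out 1 library gave 5 to 15 for 24 h against 5 h. Genes called alike at both times went from 0 to 1752 without sham A5 and 5 h A4.

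From the exon-counting libraries (3386, 3244 and 1019), the letter block gave 0, 466 and 0, all cells 2237, 6418 and 2412, and the fit without 24 h B1 and D3 987 and 0 for 24 h against sham and against 5 h. For 24 h against 5 h, DESeq2 gave 2230, the compared groups alone 648, the covariate 598 and thinned sums 660. Thinned sums gave 2222 for 5 h against sham. Leaving out 1 library gave 986 to 3590, 993 to 3605 and 42 to 1495. Of the lists (8, 16 and 15), an estimated correlation left 0, 1 and 0, all cells gave 18 and 26 against sham, and fry 7 for 24 h against 5 h.

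Signs turned with all cells summed, where other cell types enter by construction: at 5 h Ccnb1 -0.0107, Gfap 0.269, Kcnj8 1.20, Abcc9 0.376, Cd44 1.49 and Lpl 0.168, and at 24 h Cdh5 2.53, Abcc9 0.664, Kcnj8 0.862, Vegfa 1.03 and Cd44 2.71. With stricter cells Mki67 at 5 h was 0.0603, and without 24 h B1 and D3 Ccnb1 at 24 h was 0.168. Leaving out 1 library gave -0.077 to 0.028 for Mki67 at 5 h and -0.013 to 0.334 for Ccnb1.

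In other classes, microglia-like cells of all 10 libraries (0, 0 and 0) gave 115, 124 and 159 with DESeq2, 41, 163 and 368 without sham A5 and 5 h A4, and 1 at 24 h without a filter, and leaving out 1 library gave 0 to 1 for 24 h against 5 h. Those of the exon-counting libraries (41, 163 and 368) gave 170, 64, 403 and 19 at 5 h with DESeq2, RLE, no filter and doublets kept, 301 and 721 at 24 h with DESeq2 and no filter, and 1076 for 24 h against 5 h with no filter. Leaving out 1 library gave 0 to 164, 1 to 656 and 102 to 648. Border macrophage or monocyte-like cells (0, 24 h against 5 h) gave 583 with DESeq2, 157 with no filter and 638 without sham A5 and 5 h A4, and 0 to 638 leaving out 1 library. Their exon-counting count (638) was 1473 with no filter and 191 to 836 leaving out 1 library. Astrocyte-like cells (13, 107 and 298) gave 183, 347 and 536 with DESeq2, 146, 347 and 601 with no filter and 42 for 24 h against sham with doublets kept, and 0 to 30, 1 to 330 and 65 to 397 leaving out 1 library. Oligodendrocyte progenitor-like cells (167) gave 526 with no filter, 95 with doublets kept and 12 to 229 leaving out 1 library, and endothelial-like cells (186) 815 with no filter and 5 to 481 leaving out 1 library. Mature granule neuron-like cells (0) gave 1 with DESeq2, 14 with no filter and 0 to 3 leaving out 1 library.

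With cells outside the lineage as the denominator, the differences in share turned for unnamed cells (-19.4, -26.6 and -7.23 points), microglia-like cells at 5 h (-0.0806) and neutrophil-like cells between the times (-1.51). Leaving out 1 library gave -0.016 to 0.474 points for mature granule neuron-like cells at 5 h. For shares of cells with a UMI, 24 h minus 5 h, Mdm2 was 9.12 points without thinning and -2.41 to 0.923 leaving out 1 library, Gli1 was 2.77 without thinning, 0.443 at 3000 UMIs and -0.576 to 0.119 leaving out 1 library, and Atoh1 was -0.603 without sham A5 and 5 h A4, -0.254 at 3000 UMIs and -0.603 to 1.17 leaving out 1 library. With unnamed clusters 23, 26.1, 35 and 37 given the class of their highest list, the astrocyte-like share in sham was 1.001%, against 0.609%. Other repeats of shares kept their direction.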

Other observations

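Inflammatory and p53 lists were also called at the preset correlation in several of the classes described above. None of the list calls given in this section held with an estimated correlation. In astrocyte-like cells of the exon-counting libraries, 2 of 28 p53 targets rose at 5 h, 8 when adjusted over the list alone (median 0.87, camera adjusted p = 1.44e-12, adjusted p = 0.272 with an estimated correlation). Of 17 NF-kB genes 9 fell between 5 h and 24 h, 16 when adjusted over the list alone (median -2.03, camera adjusted p = 2.78e-23, adjusted p = 0.131 with an estimated correlation). At 24 h against sham, 7 of 44 genes of G2 and M phase fell in these cells, while adjusted over the list alone 28 fell and 1 rose (median -2.40, camera adjusted p = 3.94e-25, adjusted p = 0.427 with an estimated correlation). In the astrocyte-like cluster 8 granule-lineage markers were also detected, and the part of this fall due to RNA of tumour cells was not measured. In oligodendrocyte progenitor-like cells, 4 of 8 NF-kB genes fell between the times, 8 when adjusted over the list alone (median -2.01, camera adjusted p = 9.14e-17, adjusted p = 0.283 with an estimated correlation), and 8 of 25 p53 targets fell, 17 when adjusted over the list alone (median -0.84, camera adjusted p = 1.42e-16, adjusted p = 0.283 with an estimated correlation). In border macrophage or monocyte-like cells 9 of 19 p53 targets fell, while adjusted over the list alone 12 fell and 1 rose (median -1.07, camera adjusted p = 2.46e-08, adjusted p = 0.0768 with an estimated correlation).

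In endothelial-like cells 5 of 14 NF-kB genes fell between 5 h and 24 h, 13 when adjusted over the list alone (median -2.22, camera adjusted p = 1.90e-09, adjusted p = 0.392 with an estimated correlation), and Ccl2 fell from 741 to 12.9 CPM (log2 -5.40 ± 0.95, edgeR adjusted p = 0.0218). Markers of fibroblasts (median -4.66) and of microglia (-2.91) fell in the same sums, and so did the haemoglobin genes Hbb-bs (-6.69) and Hba-a1 (-6.49). In microglia-like cells 7 of 24 p53 targets rose at 24 h against sham, while adjusted over the list alone 10 rose and 1 fell (median 0.74, camera adjusted p = 2.00e-06, adjusted p = 0.103 with an estimated correlation), while the growth-differentiation factor gene Gdf15, a p53-responsive stress gene, rose by 3.95 and Ccnd2, a G1 cyclin, fell by 3.06 on the log2 scale.

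Among neutrophil-like cells, which the tests did not cover, Cdkn1a was at 195, 308 and 483 CPM in 5 h B2, C1 and C2, and at 379 and 121 CPM in 24 h A3 and B1. In T or NK-like cells it was at 102 CPM in 5 h C1 (31 cells) and at 34.2 and 51.0 CPM in 24 h A3 and B1 (35 and 37 cells). No sham library had enough cells of either class, and the part of these levels due to free RNA of other cells was not measured.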
